A study of Mus musculus with 5 samples.

How the data were processed

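CD11b+ macrophages were sorted with a FACSAria instrument from Matrigel plugs on day 8 in mice aged 7 to 12 weeks, per the labels' protocols, and total RNA was extracted with Trizol. Biotinylated cRNA was made from 6 µg of total RNA by the Affymetrix protocol and hybridised, per the labels. The authors deposited 1 table of linear signal intensity per probe set on 5 arrays; the software, the summary of probes into probe sets and the scaling are not given in the sources used here. From the values, the mean of each array after removal of 2% at either end was 100.0, so that a global scaling was in place before deposit, while array medians still differed by up to 1.47 times.

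Each array was scaled to the median over arrays of the array medians, because they differed by more than the limit of 1.1 times set before the data were examined. The 64 control probe sets were removed, values under the pooled 25th percentile of scaled signals (4.79) were raised to it, log2 was taken, and 3984 probe sets at the floor on all 5 arrays were not tested. The remaining 41053 were compared with limma (lmFit and eBayes without trend, two-sided, Benjamini-Hochberg adjusted p under 0.05) in R, with no covariate. Values below the floor have no order, so log2 differences of such genes are bounds. This also holds where the text marks no bound, as for Eomes, Mcpt8, Cd247, Uty, Gp9, Pax5 and Siglech. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9. Arrays give no counts, so no depth is stated.

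Gene names came from the platform annotation: 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none, and the latter 2 kinds are called unnamed. Symbols were checked through the Entrez identifier against RefSeq genes of assembly GRCm38.p6, which changed 0 of them. A gene's value is that of its named probe set with the highest mean log2 over all arrays, giving 17074 genes.

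Fixed gene lists were tested with camera (correlation preset at 0.01) against all other named genes, adjusted over 14 main and other lists and separately over 15 marker lists, and again with an estimated correlation; fry was run beside it. The main lists were interferon-gamma response, class II and class I presentation, classical and alternative activation and cytotoxic effectors. The other lists were type I interferon response, chemokines, cell cycle, angiogenesis and matrix remodelling, glycolysis and hypoxia, lipid handling, complement and Fc receptors, and inhibitory molecules. The marker lists covered macrophage, inflammatory monocyte, neutrophil, eosinophil with mast cell and basophil, dendritic cell, T cell, natural killer cell, plasma cell or myeloma, B cell, fibroblast, endothelial, erythroid or platelet, keratinocyte or adipocyte, immediate-early and stress, and sex-linked genes. List members with no named probe set tested, such as Gbp4 and Gbp5, are not analysed here. Some genes are in several lists, so the list results are not independent of each other. The interferon-gamma list shares Psmb9 and Nlrc5 with class I, Ciita with class II and Fcgr1 with complement and Fc receptors. It also shares members with the chemokine and inhibitory lists, and other pairs of lists overlap too.

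Named genes were chosen by a rule written before the data were examined: up to 12 genes per direction with the largest log2 difference among those past the threshold, with the groups fully apart and the higher group's mean above the median; in each main list up to 4 and in each other or marker list up to 2 members past the threshold, or the 2 with the largest absolute difference where fewer pass; and Nos2, Arg1, Cxcl9, Cxcl10, Ciita, Gzma, Gzmb, Tnf, Il12b and Mrc1 whatever their result. Members of a list named beyond this rule are examples picked after their values were seen.

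The spike-in control probe sets split the arrays into batch A (tumoricidal replicates 1 and 2, control replicate 1) and batch B (tumoricidal replicate 3, control replicate 2): BioC signals in B were 0.283 and 0.251 times those in A, Lys 1.84 times, Phe 1.77 times and Dap 1.35 times. As both batches hold both groups, values are given within each and with the batch as a block; batch B holds 1 array per group. The difference between 3' and 5' probe sets, which rises with RNA degradation, was between -0.35 and -0.17 (log2) for Gapdh and between 0.28 and 0.56 for Actb, the highest in control replicate 1.

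The test was tested on simulated data with the real levels and spreads, where 335, 335 and 330 probe sets, all above the median, were changed by log2 1, 2 and 4. With all probe sets, 0%, 16.1% and 66.4% of these were recovered, with 3.87% false calls; with only probe sets above the median the shares were 0.597%, 44.5% and 89.1%, with 4.30% false calls. Camera found 20 of 20 simulated lists shifted by 1 and 0 of 20 without a shift. The simulated genes were drawn independently of each other, so false calls from correlated genes could not show there. In the real data the estimated correlation was 0.44 for the interferon-gamma list.

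Alternatives fixed before the data were examined were quantile normalization, centring of log2 values, only probe sets above the median, log2(value + 16) with no floor, a floor at the 50th percentile, eBayes with trend and robust, array weights, the replicate number as a block, each array left out, the mean over all probe sets of a gene, and stricter thresholds. Chosen after seeing the data were the deposited scaling, the batch as a block, each of these together with the filter, and flooring before centring.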

Results

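Gene expression was measured in macrophages that had entered subcutaneous Matrigel plugs, a gelled matrix that holds injected cells in place, in Balb/c SCID mice carrying a transgenic T-cell receptor. SCID mice make hardly any B and T cells of their own, and the transgenic receptor recognises the idiotype of MOPC315, that is, a piece of the antibody which this mouse myeloma line makes. Plugs held either MOPC315 cells or an antigen-loss variant of the line. CD11b+ cells were sorted on day 8. The labels name the cells from MOPC315 plugs tumoricidal macrophages (3 arrays, biological replicates) and those from antigen-loss plugs control macrophages (2 arrays). Median signals were 17.7, 18.7 and 15.4 in tumoricidal replicates 1 to 3 and 22.6 and 18 in control replicates 1 and 2. Across the tested probe sets the log2 signals of any pair of arrays correlated with Pearson's r between 0.941 and 0.965, where probe sets are not independent replicates, and the highest value was between tumoricidal replicate 3 and control replicate 2. The number of arrays limits the precision of every value below. The design text gives 1 comparison, between macrophages that shared a plug with cells bearing the T cells' antigen and macrophages that did not.

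Tumoricidal macrophages carried far more RNA of interferon-inducible genes than control macrophages. Cxcl9, a chemokine that draws activated T cells, had a mean signal of 4310.4 ± 1151 (SD, n = 3) against 65.3 ± 12.0 (SD, n = 2), a log2 difference of 6.02 (SE 0.31, limma adjusted p = 0.0270). The guanylate-binding proteins, GTPases induced by interferon, rose with it: Gbp8 by 4.62, Gbp6 by 4.46, Gbp2b by 3.96 and Gbp2 by 3.82 on the log2 scale. Sectm1a rose by 4.31. Plet1 rose by at least 3.85, with 1 control array at the floor. The uridine phosphorylase Upp1 rose by 3.54 and the macrophage surface receptor Slamf8 by 3.42. Trap1a fell by at least 3.29, with 1 tumoricidal array at the floor. Dppa4, a gene of pluripotent cells, was at least 8.33-fold lower, since its 3 tumoricidal arrays were all at the floor. Whether the RNA of Trap1a and Dppa4 in the control samples came from macrophages or from myeloma cells in the sort was not tested.

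Of 41053 probe sets, 14 were higher and 7 lower in tumoricidal macrophages at limma's adjusted p under 0.05. The 14 came from 9 named genes and 2 unnamed probe sets, and the 7 from 4 named genes and 3 unnamed probe sets. Cxcl9, Gbp2 and Gbp6 were each called on both of their probe sets. The other 2 named genes called lower, Pkp2 and Cxcl14, fell outside the naming rule and were picked out after their values were seen: another probe set of each, with a higher mean, was not called (Pkp2 log2 difference -2.44, adjusted p = 0.292; Cxcl14 -0.82, adjusted p = 0.744). Each of the 7 probe sets called lower had at least 1 tumoricidal array at the floor, and 4 had all 3 there. At an unadjusted p under 0.05 there were 2021 higher and 1259 lower probe sets, a balance that depends on the scaling: 1731 and 1693 with quantile normalization, and 1172 and 2500 with the deposited scaling. Both groups were fully apart at 20.9% of probe sets. Chance gives at most 20%, as ties at the floor can only lower that share, and how far they lower it was not tested. With the batch seen in the spike-in control probe sets as a block, or with any single array left out, limma called 0 probe sets, while keeping only probe sets above the median called 194 higher and 28 lower. Within the batches the Cxcl9 difference was 5.90 in batch A and 6.08 in batch B, and 5.98 with the batch as a block (adjusted p = 0.145, shared by the other 10 called genes in the naming rule). The block left Gbp8 at 4.73, Gbp6 at 4.54, Sectm1a at 4.38, Gbp2b at 4.005, Plet1 at 3.79, Gbp2 at 3.84, Upp1 at 3.53, Slamf8 at 3.46, Trap1a at -3.30 and Dppa4 at -3.04.

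**Figure D1:**
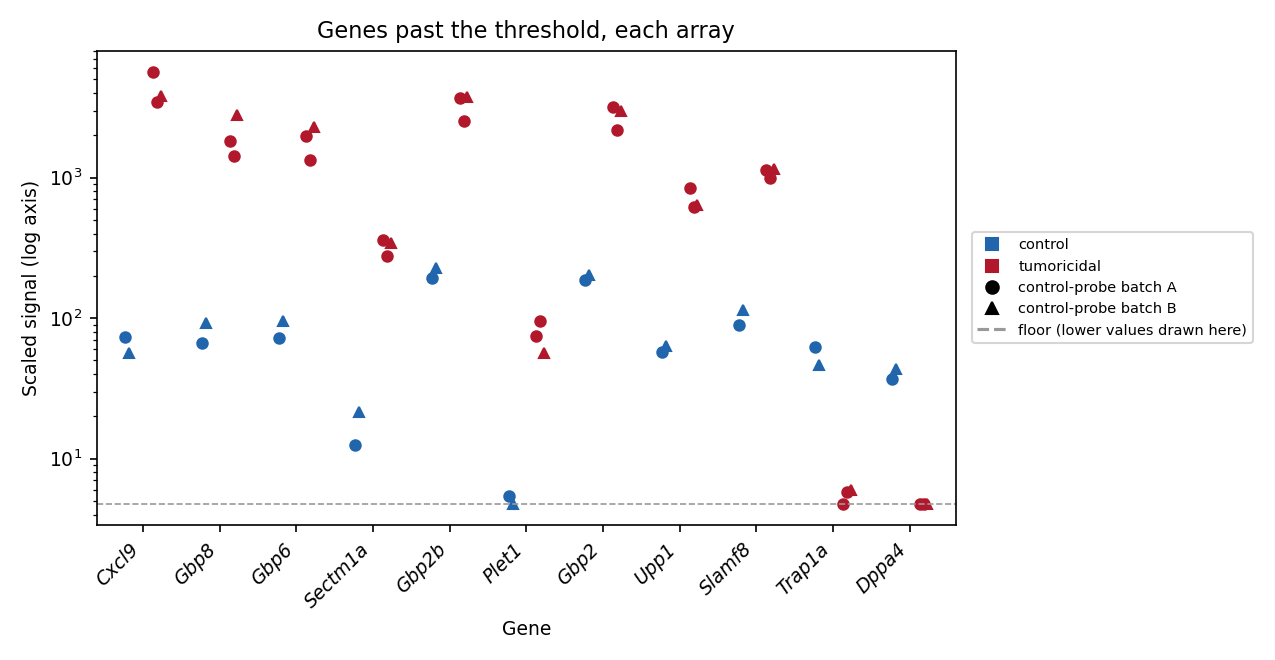
Scaled signal (log axis) of the 11 named genes past the threshold, 1 point per array, control in blue and tumoricidal in red, with the symbol giving the control-probe batch and the dashed line the floor. For the 9 genes called higher each tumoricidal array lies above both control arrays, and for Trap1a and Dppa4 each lies below them.

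The interferon-gamma list, fixed before the data were examined, moved as a whole. All 32 measured members had positive log2 differences, with a mean of 2.35, and in 31 every tumoricidal array exceeded both control arrays. Over all probe sets 4 members rose (Cxcl9, Gbp6, Gbp2 and Slamf8) and 28 did not pass; adjusted over the list alone, 30 rose and 0 fell. Those 30 included the immunity-related GTPases Iigp1 (2.79), Igtp (2.70) and Irgm2 (2.54), the transcription factor Irf1 (2.49), the signalling inhibitor Socs1 (3.53), and the checkpoint ligand Cd274 (2.18). Cxcl10, named in advance, had a log2 difference of 1.96 (adjusted p = 0.175 over all probe sets). The list was higher than other genes by camera with a preset correlation (adjusted p = 2.3e-39), but not with an estimated correlation (p = 0.0278, adjusted p = 0.345). The mean was 2.31 within batch A, 2.47 within batch B and 2.38 with the batch as a block. None of the camera calls below held after adjustment with an estimated correlation, where the lowest adjusted p was 0.345 among the main and other lists and 0.643 among the marker lists.

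Antigen presentation genes were higher too. In the class I list, 0 of 17 measured members passed over all probe sets, and adjusted over the list alone 10 rose: among them the peptide transporters Tap1 (2.46) and Tap2 (2.27) and the immunoproteasome subunits Psmb9 (2.32), Psmb10 (1.91) and Psmb8 (1.79). The heavy chains H2-K1 (0.50) and H2-D1 (0.45) and B2m (0.42) did not pass. The class I mean was 1.28 (camera adjusted p = 6.6e-12; p = 0.133 with an estimated correlation), 1.43 within batch A, 1.22 within batch B and 1.34 with the block. In the class II list, 0 of 12 passed over all probe sets and 7 rose when adjusted over the list alone, led by the peptide-loading chaperones H2-DMb2 (2.26) and H2-DMa (2.04). The class II transactivator Ciita stood at 1.03 (adjusted p = 0.469 over all probe sets), among the 7 over the list alone. The class II mean was 1.09 (camera adjusted p = 5.1e-09; p = 0.0778 with an estimated correlation), with 1.09 and 1.11 within batches A and B and 1.1 with the block.

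The classical (M1) activation list was higher with a mean of 0.96 (camera adjusted p = 9.1e-08; p = 0.148 with an estimated correlation), 0.77 within batch A, 1.44 within batch B and 1.05 with the block. None of its 26 measured members passed over all probe sets. Adjusted over the list alone 8 rose, among them Il12a, Inhba and Acod1, which makes itaconate (1.99). The interleukin subunit Il12a rose by at least 3.17, with 1 control array at the floor. The activin subunit Inhba rose by 2.76, but by 2.02 without tumoricidal replicate 3. Its signals were 228, 222 and 1058 in tumoricidal replicates 1 to 3. Nos2, the inducible nitric oxide synthase, had signals at the floor in both control arrays and a log2 difference of 1.43 (adjusted p = 0.783). Its tumoricidal signals were 10.1, 5.39 and 39.3 in replicates 1 to 3, and without replicate 3 the difference was 0.62. Tnf differed by -0.02 (SE 0.92) and Il12b by 1.05 (SE 0.45), neither past the threshold. The alternative (M2) list did not shift as a set (mean 0.41, camera adjusted p = 0.441; 0.41 and 0.54 within batches A and B, 0.47 with the block). Its members went both ways: none of 30 passed over all probe sets, and adjusted over the list alone 6 rose and 1 fell. The chemokines Ccl17 (4.67) and Ccl22 (2.49), the checkpoint ligand Pdcd1lg2 (3.87) and the beta-glucan receptor Clec7a (2.65) were among those that rose, and the growth factor Igf1 fell by 1.17. Fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.00147 for this list and was under 0.05 for all other main lists too. Fry's test for a shift in 1 direction, which asks for any change and not for more than in other genes, gave an adjusted p of 0.0146 for the interferon-gamma list, 0.0499 for class II, 0.0597 for class I, 0.146 for classical and 0.196 for alternative activation, and 0.0597 for cytotoxic effectors. Of the other lists that passed camera as higher, it gave 0.104 for type I interferon genes and for chemokines, 0.0597 for the inhibitory list and 0.196 for complement and Fc receptors. For natural killer and plasma-cell markers it gave 0.172 each. Arg1 and Mrc1, the usual markers of alternative activation, differed by 0.04 (SE 0.37) and 0.05 (SE 0.27). Tnf, Arg1 and Mrc1 each changed sign with single arrays left out (-0.90 to 0.59, -0.23 to 0.31 and -0.11 to 0.21). Il12b stayed positive but ran from 0.40 (without control replicate 2) to 1.71 (without control replicate 1).

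**Figure D2:**
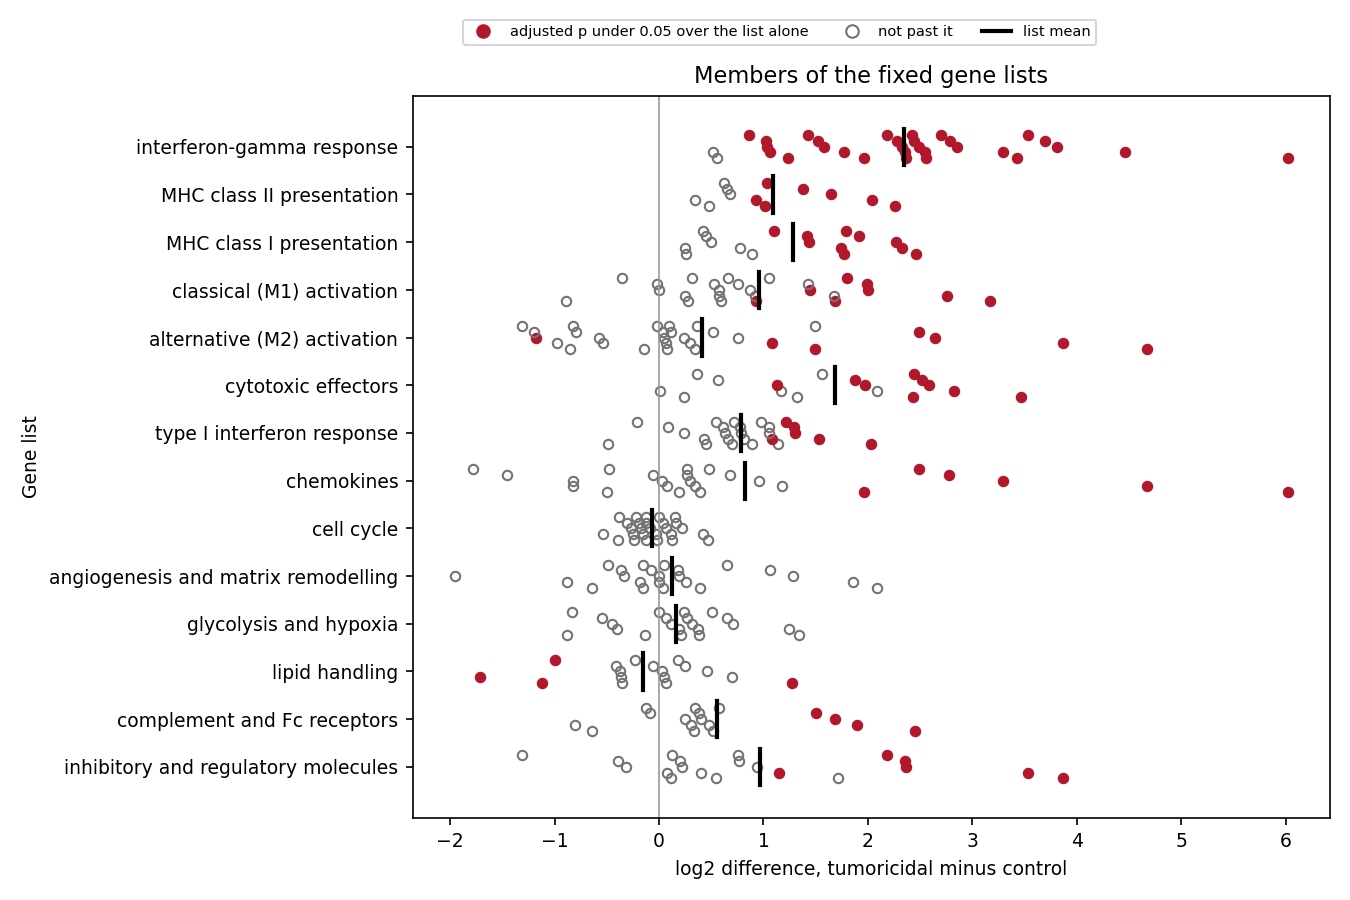
Log2 difference (tumoricidal minus control) of each measured member of the 14 main and other gene lists, 1 point per gene, filled where the adjusted p over the list alone is under 0.05, with the list mean as a black bar. The interferon-gamma list has the highest mean, 2.35, and cell cycle members lie close to 0.

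Genes of cytotoxic effectors were higher in tumoricidal samples. None of the 17 measured members passed over all probe sets, and 9 rose when adjusted over the list alone, among them granzymes B (Gzmb, 3.47) and A (Gzma, 2.82), Ifng (2.59), the activating receptor Klrk1 (2.52) and Nkg7 (2.44). Gzmb had 1146 ± 635 (SD, n = 3) against 101 ± 69.1 (SD, n = 2). Over arrays left out, Gzma ran from 1.86 (without control replicate 2) to 3.78 (without control replicate 1), and Gzmb from 2.71 to 4.23 with the same arrays. The list mean was 1.68 (camera adjusted p = 1.7e-09; p = 0.0703 with an estimated correlation), 1.82 within batch A, 1.21 within batch B and 1.56 with the block. Markers of natural killer cells were higher as well. None of 10 passed over all probe sets, and 3 rose when adjusted over the list alone, including Eomes (2.58) and Klrk1. Their mean was 1.40 (camera adjusted p = 8.7e-05, p = 0.130 with an estimated correlation), 1.55 within batch A, 0.96 within batch B and 1.30 with the block. T-cell markers had a mean of 1.22 (camera adjusted p = 0.0792; 1.60 and 0.28 within batches A and B, 1.03 with the block) and none of 13 passed in either way of adjusting. Cd3g had 185 in tumoricidal replicate 2 against 31.5 and 25.9 in the other 2 tumoricidal arrays, and Cd247 differed by 2.32 (SE 0.99), a sign shared by 2 of its 4 probe sets.

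Among the other lists, type I interferon genes were higher (mean 0.78, camera adjusted p = 6.1e-08; p = 0.173 with an estimated correlation): 0 of 26 passed over all probe sets and 6 rose when adjusted over the list alone, led by Zbp1 (2.03) and Herc6 (1.53). Of 25 chemokines, Cxcl9 passed over all probe sets and 6 rose when adjusted over the list alone, with Ccl17, Cxcl11 (3.29) and Ccl5 (2.78) among them (mean 0.82, camera adjusted p = 0.0313; p = 0.355 with an estimated correlation). The inhibitory and regulatory list was higher (mean 0.97, camera adjusted p = 0.000129; p = 0.117 with an estimated correlation), with 0 of 20 over all probe sets and 6 higher when adjusted over the list alone, including Pdcd1lg2 and Socs1. Complement and Fc receptor genes were higher as a set (mean 0.55, camera adjusted p = 0.00831; p = 0.410 with an estimated correlation), with 0 of 17 over all probe sets and 4 when adjusted over the list alone: Axl (2.45), Itgax (1.89), Cfb (1.68) and Fcgr4. The complement and Fc receptor call was lost without control replicate 1 (mean 0.28, camera adjusted p = 0.102) and without tumoricidal replicate 3 (0.39, 0.115), and the chemokine call without tumoricidal replicate 3 (0.66, 0.359) and without either control array; both were also lost with quantile normalization and the replicate number as a block. Of 2 Axl probe sets only the one used here was positive. The complement and Fc receptor list also holds genes of neither kind, among them Axl, Mertk, Gas6 and Msr1. The within-batch means for A and B were 0.62 and 0.97 for type I interferon genes, 0.69 and 1.11 for chemokines, 0.89 and 1.18 for the inhibitory list, and 0.66 and 0.62 for complement and Fc receptors. With the batch as a block these 4 means were 0.77, 0.87, 1.02 and 0.64. Cd274, Ido1, Socs1 and Il18bp of the inhibitory list are also in the interferon-gamma list. So are Cxcl9, Cxcl10 and Cxcl11 of the chemokines.

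Lipid handling genes were lower relative to other genes (mean -0.15, camera adjusted p = 0.0414; p = 0.490 with an estimated correlation): 0 of 17 passed over all probe sets, and adjusted over the list alone Lpl rose by 1.28 while Fabp4 fell by 1.71, Pparg by 1.12, and Sqle fell as well. Their mean was 0.05 within batch A and -0.26 within batch B, and -0.08 with the block, where the list no longer passed (camera adjusted p = 0.123). Cell cycle genes had a mean of -0.07 (camera adjusted p = 0.0472; p = 0.582 with an estimated correlation), with 0 of 27 members past either adjustment; Cenpe differed by -0.54 and Aurkb by 0.47. The mean was 0.13 within batch A, -0.18 within batch B and -0.00257 with the block (camera adjusted p = 0.139). Aurkb had 0.99 within batch A and -0.15 within batch B. Over arrays left out, the cell cycle mean ran from -0.36 (without control replicate 1) to 0.22 (without control replicate 2), and Aurkb from 0.05 to 0.89 with the same arrays. The cell cycle call was also lost without tumoricidal replicate 1 or 2. Glycolysis and hypoxia genes (21 measured, mean 0.16, camera adjusted p = 0.539) had no member past either adjustment, with Hk3 at 1.34 and Pfkp at 1.25; within batches A and B their means were 0.34 and 0.16, and 0.26 with the block, while single arrays left out moved the mean from -0.20 (without control replicate 1) to 0.52 (without control replicate 2). Angiogenesis and matrix genes (23 measured, mean 0.12, camera adjusted p = 0.539, direction down although the mean was positive) also had none, with Mmp12 at 2.08 and Thbs1 at -1.96; their means were 0.07 and 0.39 within batches A and B and 0.20 with the block, and from -0.0870 (without tumoricidal replicate 3) to 0.31 (without tumoricidal replicate 2) over arrays left out.

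Markers of plasma cells, the cell type of the injected myeloma, were lower in tumoricidal samples (12 measured, mean -1.08, camera adjusted p = 0.000121; p = 0.171 with an estimated correlation). None passed over all probe sets, and adjusted over the list alone 2 fell: Pou2af1, a B-lineage coactivator, by 3.24 (55.1 ± 12.7, n = 3, against 514 ± 43.4, n = 2, SD) and Tnfrsf17 by 2.65, with all 3 tumoricidal arrays at the floor. Jchain, the joining chain of secreted IgA, differed by -2.80 (SE 0.85, adjusted p = 0.480). The mean was -1.13 within batch A, -0.78 within batch B and -0.98 with the block. Macrophage markers did not pass as a set (mean 0.35, camera adjusted p = 0.121; 0.49 and 0.34 within batches A and B), with Aif1 at 1.14 and Fcgr3 at 0.57. Neutrophil markers had a mean of 0.60 (camera adjusted p = 0.0919; 0.80 and 0.40 within batches), with Cxcr2 at 1.47 and Lcn2 at 1.22. Markers of eosinophils, mast cells and basophils had a mean of 0.67 (camera adjusted p = 0.0934; 0.51 and 0.76 within batches), and adjusted over the list alone the basophil protease Mcpt8 rose by 3.33 and the eosinophil lectin Siglecf by 2.28. With the batch as a block these 3 means were 0.42, 0.63 and 0.62.

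The remaining marker lists did not pass camera. Dendritic cell markers had a mean of 0.30 (camera adjusted p = 0.687), where adjusted over the list alone 2 rose, Ccl22 among them, and 1, Siglech, fell by 1.66; the within-batch means were 0.20 and 0.32 and the blocked mean 0.25. Inflammatory monocyte markers had a mean of -0.33 (camera adjusted p = 0.405; -0.25 and -0.63 within batches, -0.41 blocked), with Cx3cr1 at -2.39 and Plac8 at 0.89. B-cell markers had -0.19 (0.340; -0.44 and 0.05, -0.23 blocked), with Cd79b at -0.91 and Pax5 at -0.27. Fibroblast markers had -0.20 (0.121), with opposite signs within batches, -0.85 in A and 0.82 in B, and -0.14 blocked; Lum stood at -0.68 and Fap at -0.51. Endothelial markers had a mean of 0.10 (0.758, direction down; 0.24 and -0.11 within batches, 0.09 blocked), with Vwf at 0.96 and Eng at 0.76. Erythroid and platelet markers had -0.39 (0.121; -0.20 and -0.47, -0.32 blocked), and adjusted over the list alone the platelet chemokine Ppbp fell by 2.12, with Gp9 at 0.78. Keratinocyte and adipocyte markers had -0.18 (0.340; -0.27 and -0.08, -0.19 blocked), where Fabp4 was the only member past the threshold over the list alone and Krt10 stood at 0.50. Immediate-early and stress genes had -0.06 (0.340; -0.23 and 0.35, 0.01 blocked), with Hspa1a at -0.92 and Hspa1b at -0.59. Single arrays moved several of these values. Over arrays left out, the monocyte mean ran from -0.48 to -0.11 (without tumoricidal replicate 3) and Cx3cr1 from -3.003 (without tumoricidal replicate 2) to -1.43 (without tumoricidal replicate 3). The B-cell mean ran from -0.46 (without control replicate 2) to 0.0704 (without control replicate 1) and Pax5 from -1.12 to 0.58 with the same arrays. Cd79b ran from -1.29 (without tumoricidal replicate 3) to -0.24 (without tumoricidal replicate 2). Lum ran from -1.08 (without tumoricidal replicate 1) to 0.078 (without tumoricidal replicate 2), and Gp9 from -0.095 (without control replicate 1) to 1.66 (without control replicate 2). The keratinocyte and adipocyte mean ran from -0.41 (without tumoricidal replicate 1) to 0.0587 (without tumoricidal replicate 2), dendritic cell markers from 0.14 to 0.46, endothelial markers from 0.0182 to 0.18, and erythroid and platelet markers from -0.67 to -0.11. In this paragraph a bare value in brackets after a mean is the camera adjusted p.

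Sex-linked genes did not pass camera as a list, but members differed between the groups when adjusted over the list alone. Of 4 measured, none passed over all probe sets, and adjusted over the list alone 3 Y-linked genes rose, Eif2s3y by 3.82, Uty by 2.46 and Kdm5d by 2.28, while Xist, which is made from an inactive X chromosome, fell by 0.88. The list mean was 1.92 (camera adjusted p = 0.121), 0.83 within batch A, 3.12 within batch B and 1.82 with the block. Eif2s3y had 219, 173 and 266 in tumoricidal replicates 1 to 3 and 43.4 and 5.40 in control replicates 1 and 2. The labels give no sex of the mice. In the 3 Y-linked genes every tumoricidal array exceeded both control arrays. A difference in sex between the groups can therefore not be told apart from the type of plug, in any comparison here.

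**Figure D3:**
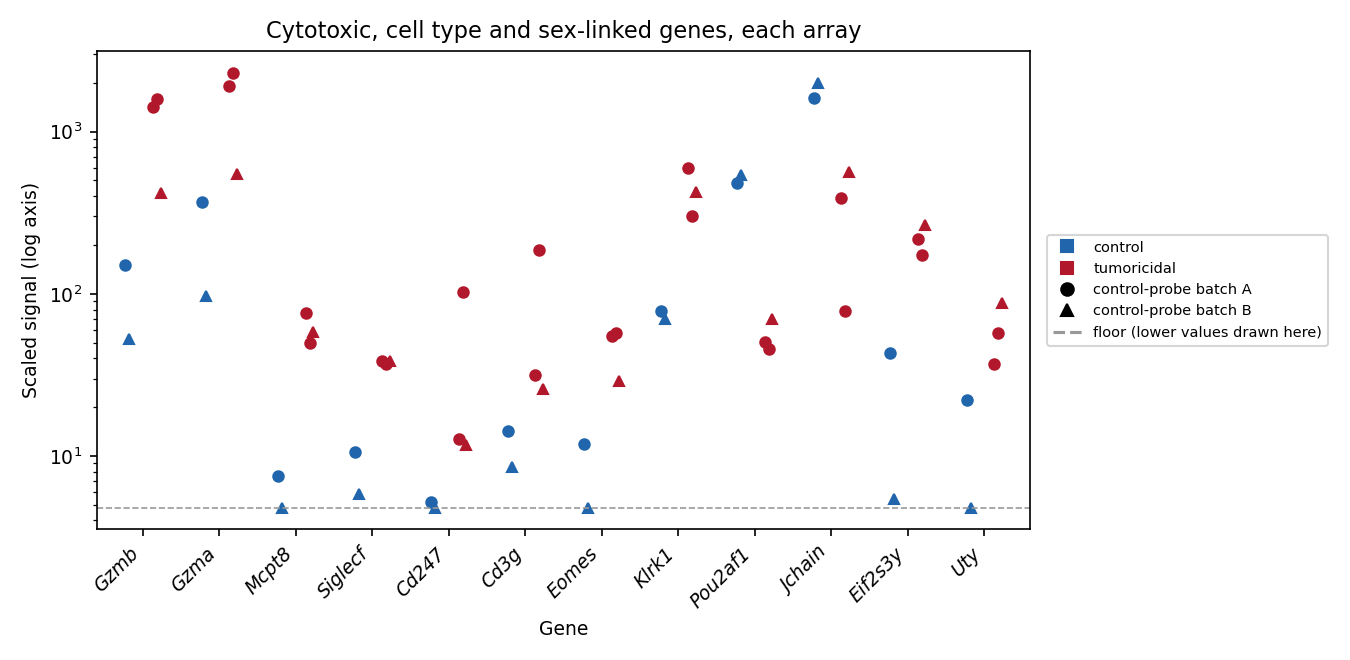
Scaled signal (log axis) of cytotoxic, cell type marker and sex-linked genes named by the rule, 1 point per array, control in blue and tumoricidal in red, with the symbol giving the control-probe batch and the dashed line the floor. Pou2af1 and Jchain are lower in each tumoricidal array than in both controls, and Cd247 and Cd3g are highest in tumoricidal replicate 2.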

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

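The tests of T-cell markers, of the control-probe batch, of the scaling and of other splits of the arrays were chosen after the results were seen, as were the limit of 2 times the highest control array and the demand that a marker list with a large mean also pass camera. The tests of natural killer and plasma-cell markers were written before their list means were known, though prompted by genes already noticed in these data.

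Among 19 control probe sets of mouse RNAs, which no comparison uses, 2 had a tumoricidal array over that limit. The 5' probe set of 18S ribosomal RNA had a deposited signal of 8333.1 in tumoricidal replicate 1 against 1680.3 and 299.2 in control replicates 1 and 2, while the 3' and middle probe sets of the same RNA had 578.9 and 466.9 there, between control replicate 1 (1423.2 and 1448.1) and control replicate 2 (240.6 and 229.8). A middle probe set of pyruvate carboxylase had 22.8, 11 and 22 in tumoricidal replicates 1 to 3 against 7.3 and 6.5 in the controls, while its other 3 probe sets showed no such difference (3': 20.8, 5.4 and 17.6 against 19.4 and 15.4; 5': 30.5, 24.4 and 32 against 22.6 and 29.9; the other middle one: 2.2, 1.4 and 2 against 2.4 and 4.6).

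Cytotoxic effector genes were higher in tumoricidal samples, and the lower of their within-batch means, 1.21, argues against the control-probe batch as the cause. Natural killer cells, which can carry CD11b and so need not be lost in the sort, are a candidate source: without Klrk1, which both lists hold, their markers had a mean of 1.27 over 9 genes (whole list: camera adjusted p = 8.7e-05, but 0.101 without control replicate 2), with Klrg1 (95.3 against 42.5) and Klrd1 (82.8 against 32.7) the most abundant. T cells, which a CD11b sort would mostly remove, stay open: their mean of 1.22 met the bound of 1 written for it, but the list did not pass camera (adjusted p = 0.0792) and the mean was 0.28 within batch B and 0.37 without tumoricidal replicate 2, though it passed in other settings (adjusted p = 0.0121 with quantile normalization). Per array, the cytotoxic list had mean log2 levels of 6.26, 6.51 and 5.38 in tumoricidal replicates 1 to 3. Natural killer markers had 5.57, 5.08 and 4.48 there, and T-cell markers 4.56, 6.81 and 3.99. The cytotoxic list and T-cell markers were thus highest in replicate 2, natural killer markers in replicate 1, and all were lowest in replicate 3. Expression of the cytotoxic genes by the macrophages themselves was not tested.

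Plasma-cell genes were lower in tumoricidal samples, and the within-batch mean nearer to 0, -0.78, argues against the control-probe batch. Myeloma RNA in the control sort cannot be told apart from other causes: without Pou2af1 the mean was -0.89, between the bounds of -1 and -0.5 written for it. The most abundant members were mixed, with Xbp1 at 0.30 and Iglv1 at -2.21, where the other Iglv1 probe set had 5.50. The probe sets of Igha, another member, differed by -0.24, -0.13 and -0.39 (SE 0.80, 0.77 and 0.85). Igha and Iglv1 are antibody genes, and the antigen lost by the control line is a piece of the MOPC315 antibody. Both tumour lines may thus differ in these genes themselves, so the list mean cannot decide on myeloma RNA. A CD11b sort would remove most myeloma cells, and a different number of tumour cells in the plugs was not tested.

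The interferon-gamma list was higher in tumoricidal samples. Its lower within-batch mean was 2.31 and its lowest mean under the median, deposited and quantile scalings 2.11, which argue against the batch and the scaling as the cause. Exposure to antigen-bearing tumour cells, which the design gives, and the sex of the mice stay open and were not tested.

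Of the 10 splits of the 5 arrays into 3 and 2, 1 gave as many called probe sets as the real one, itself: the real split gave 21 and the highest of the others 0. So few splits cannot give a share under 0.05. At an unadjusted p under 0.05 the real split had 3280 probe sets, and 2 other splits had more: 3680 for the split that follows the control-probe batch and 3883 with tumoricidal replicate 2 and control replicate 1 as the smaller group.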

How the results depend on the processing

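The deposited scaling, the batch as a block, their combinations with the filter, and flooring before centring were chosen after the data were seen. Against 14 probe sets higher and 7 lower, limma called 42 and 16 with centred log2 values, 91 and 21 with flooring before centring (81.3% higher, against 66.7%), 194 and 28 with only probe sets above the median, 59 and 12 with log2(value + 16), 48 and 12 with the floor at the 50th percentile, 177 and 25 with trend and robust, 2 and 3 with array weights, 318 and 42 with the filter and the batch block, and 108 and 29 with the filter and the deposited scaling. It called 0 and 0 at an adjusted p under 0.01, 0 and 0 with the batch as a block (2631 and 1486 unadjusted), and 0 and 0 with the replicate number as a block (1103 and 933 unadjusted, lowest adjusted p 0.908). Leaving out any 1 array also gave 0 and 0, whichever it was (lowest adjusted p from 0.104 to 0.433). All 21 calls kept their sign wherever tested. The filter tests fewer probe sets of low signal, and leaving out an array takes away a residual degree of freedom; where a control array goes, the lone one is assumed to vary like the other group. For the other changes the cause was not tested. The deposited scaling moved the median log2 difference of all probe sets from 0.086 to -0.105.

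Deviations from the group means correlated across genes at 0.02 for both arrays numbered 1 and at -0.24 for those numbered 2. With 2 control arrays, the deviations of 1 are the negative of the other's, so each sign only tells which control an array leans to. Tumoricidal replicates 1 to 3 each leaned to the control of their own batch (0.02, 0.24 and 0.26). These values do not settle whether the numbers pair the samples. With the correlation preset at 0.01, all main lists but alternative activation passed camera in every setting, and alternative activation in none. With an estimated correlation, run in the main setting only, no main list passed camera (lowest adjusted p 0.345). The changes below are also for the preset correlation. The other lists changed sides of the threshold as follows, and the cause was not tested. Chemokines no longer passed with quantile normalization (0.57), the filter (0.81), the higher floor (0.76), the replicate block (0.66), the mean of all probe sets (0.66), the filter with batch block (0.87) or with deposited scaling (0.58), or without tumoricidal replicate 3 or either control (0.66 to 0.99 over arrays left out). Cell cycle genes no longer passed with the mean of all probe sets (0.00153), the batch block (-0.00257), or without tumoricidal replicate 1 or 2 (-0.36 to 0.22), and turned to 0.22 without control replicate 2. Lipid handling no longer passed with the batch block (-0.0848) or without tumoricidal replicate 2 or control replicate 2 (-0.45 to 0.14). Complement and Fc receptors no longer passed with quantile normalization (0.25), the replicate block (0.39), the filter with batch block (0.64), or without tumoricidal replicate 3 or control replicate 1 (0.28 to 0.83). Natural killer markers no longer passed without control replicate 2 (1.13 to 1.68).

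Other marker lists passed only in some settings. Neutrophil markers did with quantile normalization (0.47), the filter (0.77), log2(value + 16) (0.52), the replicate block (0.60), the deposited scaling (0.38), the filter with batch block (0.81) or deposited scaling (0.54), and without tumoricidal replicate 3 (0.40 to 0.80). Eosinophil, mast cell and basophil markers did with quantile normalization (0.67), the filter (2.01), the higher floor (0.73), the replicate block (0.74), the deposited scaling (0.49), the filter with batch block (1.99) or deposited scaling (1.78), and without tumoricidal replicate 3 or control replicate 1 (0.44 to 0.98). With the filter alone only 2 of these 12 genes were tested, and Mcpt8 (61.3 against 3.89) stayed in through its tumoricidal signals, so the filtered means say little of the list. T-cell markers did with quantile normalization (1.21), log2(value + 16) (0.81), the replicate block (1.78), the deposited scaling (1.0), flooring before centring (1.23), and without tumoricidal replicate 1 or 3 (0.37 to 1.78). Fibroblast markers did with the filter (-0.20), the replicate block (-0.56), the filter with batch block (-0.14), and without tumoricidal replicate 3 or control replicate 2 (-0.56 to 0.23). Erythroid and platelet markers did with the filter (-0.98), log2(value + 16) (-0.47), the higher floor (-0.71), and the filter with batch block (-0.92) or deposited scaling (-1.21), and the filter alone left 3 of 5 genes. Immediate-early genes did with quantile normalization (-0.37), the replicate block (-0.30) and without tumoricidal replicate 3 (-0.30 to 0.14), sex-linked genes with log2(value + 16) (1.16) and without control replicate 1 (0.95 to 2.89), and macrophage markers without tumoricidal replicate 2 (0.0810 to 0.61).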

Other observations

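Beyond the lists, keeping only probe sets above the median, an alternative fixed before the data were examined, called 133 named genes higher and 16 lower in tumoricidal macrophages. Counted with 1 probe set per gene, they included 21 of 31 tested members of the interferon-gamma list. Of the presentation lists, 8 of 17 class I and 3 of 12 class II members were called. So were 3 of 7 cytotoxic effectors, 4 of 29 alternative and 2 of 24 classical activation members, and 6 of 24 chemokines. Among markers, 2 of 6 natural killer and 2 of 8 dendritic cell genes were called, and Eif2s3y and Mcpt8 as single members of their lists. All of these were higher. Pou2af1, lower, was the only plasma-cell marker called in this way of counting. Probe sets not used for their gene's value were called higher too, such as another of the plasma-cell marker Iglv1 (5.50) and another of Ciita (1.77). No member of the cell cycle, glycolysis, lipid or angiogenesis lists was called there. This filter depends on the change itself: of the main calls it kept all 14 higher probe sets but only 1 of the 7 lower ones, and genes near 0 in controls, such as Ubd (63.8 against 2.55), stayed in through their tumoricidal signals. The balance of higher and lower calls under it is therefore no measure of direction.

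Per array, the interferon-gamma list had mean log2 levels of 7.46 and 7.58 in control replicates 1 and 2, while Uty had scaled signals of 22.2 and 0.50 in them. In tumoricidal replicates 1 to 3 the list had 9.99, 9.56 and 10.05.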
